A study of Mus musculus with 9 samples.

How the data were processed

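The series holds 9 polyA-selected mouse RNA-seq libraries in 3 groups of 3, grouped by their titles as Vehicle, CON-BDEV and SE-BDEV. Library names in the labels (CON, EV Saline and EV Pilo, each with a code) match the columns of the deposited tables. The series design text names BV2 cells, whereas the source and cell line labels name N2a cells, and no library was moved or relabelled. Per the labels' protocols, total RNA was isolated with a ReliaPrep kit and libraries were made with a directional kit after polyA selection. Nothing in the labels says whether the replicates are separate cultures or whether replicate numbers pair libraries across groups.

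Per the labels' processing notes, the authors used TopHat2 and Cuffdiff with genome build mm9, with no versions and no annotation stated. The deposited FPKM tables, made by the authors, hold 1 value for each of 24318 genes in each library, in 1 table of CON-BDEV with Vehicle and 1 of SE-BDEV with Vehicle. The Cuffdiff tables deposited by the authors give, per the file headers, mean FPKM per group and the log2 fold change of vesicles over Vehicle. The same tables deposited by the authors give Cuffdiff's test score for each gene. They also give the authors' p-value and q-value for each gene, and Cuffdiff's status for the estimate. The same 3 Vehicle libraries appear in both FPKM tables and differ between them by 1 constant factor each (1.00042, 1.00012 and 1.00078), so the tables were joined after the SE-BDEV libraries were divided by the geometric mean of these factors. Coordinates are mm9. The listed starts behave as counted from 0, so 1 was added and printed starts count from 1. There are 100 entries that name several genes, and loci of overlapping genes can be merged.

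The files hold no read counts, so depth was estimated. A single fragment is worth the same FPKM in a gene in every library apart from depth, and the ratios of the lowest values between libraries gave relative depths of 0.877 (CON-BDEV replicate 2) to 1.01 (Vehicle replicate 2) of Vehicle replicate 1. The comparison used values under 0.05 FPKM. The smallest step of 18 genes with 1 annotated transcript and at least 4000 nt of exons gave a median of 33181000 fragments for Vehicle replicate 1. At that depth 66.4 fragments stand behind 1 FPKM in a gene with 2 kb of exons. The 10 genes with the highest values took 6.32% (CON-BDEV replicate 1) to 9.80% (Vehicle replicate 1) of a library's summed FPKM, and part of that difference comes from ferritin genes listed at 0 with the status for too many fragments. Genes with that status in a comparison's libraries were left out of it.

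Values were analysed as log2(FPKM + 1) with R 4.3.3 and limma 3.58.1, as FPKM values are not counts. Genes with a mean of at least 1 FPKM over the libraries in the fit were kept. Each vesicle group was compared with Vehicle within its own table (lmFit, eBayes with a mean-variance trend, 2-sided), and SE-BDEV with CON-BDEV in 1 fit of all 9 joined libraries. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so single genes rest on limma's pooled spread. The replicate numbers gave no sign of pairing: the mean correlation between libraries of the same number, after group means were removed, was -0.04, and 3 of 9 libraries were closest to one of their own number. No block was used.

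Of 32 gene lists fixed before the data were examined, 27 had at least 5 kept genes and were tested with limma's camera with a preset correlation of 0.01 between genes, with an estimated correlation and limma's fry beside it. Genes named in the text follow a rule also fixed then. It takes the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups do not overlap (or, where fewer than 5 pass, the 5 with the lowest p in each direction). It adds up to 4 members of each list past the threshold with the largest changes, or where none passes up to 2 with the highest mean, and 12 microglial state genes. Clone-named and predicted genes were passed over. Any other gene is said to have been chosen after its values were seen. Cell identity was described from marker lists with no test. Effects of both preparations were compared by Pearson and Spearman correlation, covariance and overlap of calls, beside 100 simulated draws in which the vesicles had no effect and the Vehicle libraries were shared. For the overlap of calls, as many top genes by limma's t as were called were compared in each draw, a simulation added after the data were seen.

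The fits were tested on simulated data with the spread of these libraries, with 50 genes changed at each of 4 sizes. For CON-BDEV against Vehicle (10535 genes) 46.0%, 86.0%, 96.0% and 100% of genes changed 1.2-fold, 1.5-fold, 2-fold and 3-fold were recovered, with 9 false calls among 10335 unchanged genes. For SE-BDEV against Vehicle (10535 genes) these were 44.0%, 80.0%, 90.0% and 100%, with 10 false calls of 10335. For SE-BDEV against CON-BDEV (10532 genes) these were 36.0%, 94.0%, 96.0% and 100%, with 14 false calls of 10332. Genes of all sizes were changed in the same data, which loosens the adjusted threshold, so fewer may be recovered where few genes pass. A list shifted on purpose had camera adjusted p of 1.55e-58, 3.98e-66 and 1.98e-59, and the other lists past the threshold (0, 2 and 2) all shared members with it. Noise was drawn separately for each gene, so this does not show how camera with the preset correlation behaves with correlated genes. In the data the estimated correlation ran from -0.12 (neuronal markers) to 0.76 (cholesterol synthesis and SREBP targets), both with SE-BDEV against Vehicle. Lists with an estimate below the preset 0.01 also lost their call with an estimated correlation. Such a miss thus does not by itself show that correlated genes made the call.

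Alternatives were pseudocounts of 0.1 and 0.01 FPKM, no filter and a filter at 5 FPKM, quantile normalization, median centring, no mean-variance trend, the replicate number or the leading number of the library name as a block, joined or separate fits, a log2 fold change of at least 1, the authors' q, and each library left out in turn. Keeping genes with failed estimates at 0, leaving out short-RNA genes and the comparison of both preparations with Vehicle were added after the data were seen. Transcript and exon lengths came from GENCODE M21, matched by gene name and RefSeq synonym. Depth and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.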

Results

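The data were polyA-selected RNA-seq libraries of cultured mouse cells exposed to brain-derived extracellular vesicles (BDEV), membrane-bound particles that cells release and other cells can take up. There were 9 libraries in 3 groups of 3: Vehicle, which received no vesicles, CON-BDEV, which received vesicles named as control, and SE-BDEV, which received vesicles named for status epilepticus, a state of prolonged seizures. Each table listed 24318 genes in FPKM (fragments per kilobase of transcript, scaled to the size of the library). Summed FPKM ran from 600196 in SE-BDEV replicate 2 to 625660 in Vehicle replicate 1, and 10486 to 10561 genes reached 1 FPKM in a library. The sums include ferritin genes that are listed at 0 in some groups after failed estimates. Without these genes CON-BDEV was highest, with 600635 to 613894, against 586476 to 598523 for Vehicle and 586035 to 595864 for SE-BDEV. The files hold no counts. Estimated from the steps between the lowest values and the exon lengths of 18 long genes, depth ran from 29092000 fragments in CON-BDEV replicate 2 to 33645000 in Vehicle replicate 2. At those depths, 58.2 to 67.3 fragments stood behind a value of 1 FPKM in a gene with 2 kb of exons. The labels do not say whether the replicates were separate cultures, so each p-value measures only the spread between these libraries, which may be technical.

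The first question was which cells the libraries came from, because the study's design text names BV2, a mouse microglial line, whereas the cell line label of every library names N2a, a mouse neuroblastoma line. The libraries carried a microglial and macrophage profile. Of 30 microglia and macrophage markers fixed beforehand, 24 had a mean of at least 1 FPKM over the 9 libraries and 10 had at least 100. Cd68, a lysosomal protein of phagocytes, averaged 740 FPKM, Tyrobp, a signalling adaptor of myeloid receptors, 712 FPKM, and Csf1r, the receptor for the survival factor CSF1, 82.6 FPKM. Of 30 neuroblastoma and neuronal markers, 5 reached 1 FPKM, namely Uchl1 (90.2 FPKM), Nefh (77.6 FPKM), Ina (9.72 FPKM), Elavl4 (3.92 FPKM) and Gata3 (3.34 FPKM). The adrenergic genes Th and Dbh and the oncogene Mycn, all typical of neuroblastoma, were listed at 0 in every library. A listed 0 may also be a failed estimate or a matter of annotation, since Hmgcs1, a sterol enzyme chosen after its values were seen, was at 0 in all 9 libraries too. The median over a list's members was 48.2 FPKM for the microglial list and 0.00581 FPKM for the neuronal list. Each of the 9 libraries taken alone gave 23 to 24 microglial and 5 to 6 neuronal markers, so no library stood apart in these counts. They say nothing of other differences between the libraries. P2ry12 and Cx3cr1, receptors typical of microglia in the brain, averaged 0.0142 and 0.122 FPKM. Of the markers of other brain cell types, 1 of 12 astrocyte markers (Aldoc, 39.8 FPKM), 2 of 12 oligodendrocyte and myelin markers (Cnp, 10.5 FPKM, and Mbp, 1.41 FPKM) and 1 of 13 endothelial, pericyte and blood markers (Flt1, 41.1 FPKM) reached 1 FPKM, as did 3 of 20 neuronal synaptic and activity transcripts. No group test was run on these levels, and at a limit of 5 FPKM the counts were 22 microglial and 3 neuronal markers.

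CON-BDEV against Vehicle asked what vesicles from control brain did to the cells. Of 22 genes kept in the list of NRF2, a transcription factor that controls antioxidant genes, 17 rose with the vesicles and 1 fell. Of 24 kept in the list of cholesterol synthesis and SREBP targets, which also holds fatty acid synthesis genes, 15 fell and 0 rose. As lists, both missed the threshold of camera with an estimated correlation (adjusted p = 0.180 and 0.267). Both passed by fry, a different test (fry adjusted p of 0.0073 and 0.0372). Nqo1, a quinone-detoxifying enzyme, rose from 0.606 ± 0.205 to 8.39 ± 3.19 FPKM (mean ± SD, n = 3 per group), and Gclm, a subunit of the enzyme that limits glutathione synthesis, from 42.2 ± 2.02 to 181 ± 49.3 FPKM. Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 6.13 ± 0.114 to 24.8 ± 6.46 FPKM, and Hmox1, which degrades heme, from 140 ± 3.36 to 469 ± 181 FPKM. In the other direction Insig1, a sterol-responsive brake on cholesterol synthesis, fell from 78.4 ± 1.08 to 43.3 ± 7.31 FPKM, and Scd2, a fatty acid desaturase, from 595 ± 16.5 to 332 ± 57.3 FPKM. The log2 fold changes were 2.49 for Nqo1, 2.03 for Gclm, 1.82 for Slc7a11, 1.65 for Hmox1, -0.86 for Insig1 and -0.86 for Scd2, with limma adjusted p of 0.00164, 0.00105, 0.000909, 0.0114, 0.00426 and 0.00548. In mm9 coordinates, with starts counted from 1, Gclm lies on chromosome 3 from 121948475 to 121970133, Slc7a11 on chromosome 3 from 50168858 to 50247535, Hmox1 on chromosome 8 from 77617517 to 77624492, Insig1 on chromosome 5 from 28397952 to 28405202 and Scd2 on chromosome 19 from 44368166 to 44381352. The locus listed for Nqo1, chromosome 8 from 109780064 to 110082495, spans far more than 1 gene, and the authors' q for it was 0.599. The authors' log2 fold change for Nqo1 was 3.79. The added 1 FPKM shrinks the value given here, as Nqo1 was under 1 FPKM in Vehicle.

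Of the 22 NRF2 and oxidative stress genes kept, 17 rose and 1 fell with CON-BDEV (also 17 and 1 adjusted over the list alone), with a median log2 fold change of 0.63. Cat, which removes hydrogen peroxide, and Prdx1 and Gpx1, both peroxidases, were each chosen after its values were seen. Cat rose by 1.12 and Prdx1 by 1.08, and Gpx1 was the gene that fell (-0.30). The camera adjusted p was 1.53e-17, and it was adjusted p = 0.180 with an estimated correlation. Of 24 cholesterol synthesis and SREBP targets kept, 15 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -0.41, a camera adjusted p of 7.09e-17, and adjusted p = 0.267 with an estimated correlation. Fasn, the fatty acid synthase, fell by 0.57 and Lss, which forms the first sterol ring, fell by 0.54. Among 13 LXR and lipid efflux genes 5 fell and 0 rose (6 fell and 1 rose adjusted over the list alone; camera adjusted p of 0.00386, adjusted p = 0.180 with an estimated correlation), among them Srebf1, a lipid-synthesis transcription factor (-0.62), and Abca1, the cholesterol exporter (-0.49).

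Some genes of uptake and degradation rose with CON-BDEV. In the phagocytosis and lysosome list 8 of 30 genes rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p of 0.000118, adjusted p = 0.180 with an estimated correlation). Cd36, a scavenger receptor for oxidised lipids, rose from 5.05 ± 0.303 to 13.6 ± 3.43 FPKM. Lipa, the lysosomal lipase that frees cholesterol from its esters, rose by 0.77 and Itgav, an integrin, by 0.46. The alternative activation and resolution list moved unevenly, since 5 of 15 genes rose, with Hmox1 and Cd36 again the largest, while Arg1, an arginine-consuming enzyme, fell by 0.66 (8 higher and 1 lower adjusted over the list alone; camera adjusted p of 0.00238, adjusted p = 0.301 with an estimated correlation). Of the 7 chemokines kept, Ccl7 (1.43) and Ccl2 (0.86), which attract monocytes, rose and Ccl4 (-0.81) and Ccl9 (-0.68) fell (also 2 and 2 adjusted over the list alone; camera adjusted p of 0.985, adjusted p = 0.989 with an estimated correlation). The pro-inflammatory cytokine and NF-kB list had 3 of 23 genes higher and 0 lower (also 3 and 0 adjusted over the list alone), Ptgs2 (0.75), Tlr2 (0.48) and Saa3 (0.34). Its camera adjusted p of 0.0464 was 0.123 without Vehicle replicate 3, 0.342 without CON-BDEV replicate 2 and 0.0867 by fry, with adjusted p = 0.389 with an estimated correlation. Tnf and Il1b, classic inflammatory cytokines, had log2 fold changes of 0.14 and 0.27 with limma adjusted p of 0.241 and 0.122. The complement list had 3 of 10 genes higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p of 0.435, adjusted p = 0.611 with an estimated correlation), with C1qc (0.68), C1qb (0.54) and C3 (0.32) higher and C5ar1 (-0.38) lower. In the inflammasome list 1 of 11 genes rose and 0 fell, Casp1, the protease that activates interleukin 1 beta, by 0.54 (also 1 and 0 adjusted over the list alone; camera adjusted p of 0.0505, adjusted p = 0.357 with an estimated correlation).

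Of the remaining lists, 5 of 24 unfolded protein response genes rose with CON-BDEV and 0 fell (9 and 0 adjusted over the list alone), among them Herpud1 (0.54) and the chaperone Calr (0.36), with a camera adjusted p of 2.83e-05 and adjusted p = 0.180 with an estimated correlation. Oxidative phosphorylation had 1 of 28 genes higher, Ndufa2 (0.19), and 0 lower (4 and 0 adjusted over the list alone), with a camera adjusted p of 2.83e-05 and adjusted p = 0.180 with an estimated correlation. Type I interferon genes had 2 of 18 lower, Ifitm3 (-0.37) and Oas1a (-0.32), and 0 higher (also 2 and 0 adjusted over the list alone), with a camera adjusted p of 0.00617 and adjusted p = 0.180 with an estimated correlation. Both symbols belong to families of similar genes. G2/M cell cycle genes had 1 of 22 lower, Cenpf (-0.23), and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p of 3.24e-05, fry adjusted p of 0.0520, adjusted p = 0.301 with an estimated correlation). Microglia and macrophage markers had 7 of 23 higher and 1 lower (also 7 and 1 adjusted over the list alone; camera adjusted p of 0.0124, but 0.0776 without CON-BDEV replicate 1 and 0.104 after quantile normalization, and adjusted p = 0.357 with an estimated correlation). Homeostatic microglia genes had 2 of 9 higher, Cst3 (0.20), a protease inhibitor, among them, and 0 lower (also 2 and 0 adjusted over the list alone; camera adjusted p of 0.0141, but 0.0553 without CON-BDEV replicate 1, and adjusted p = 0.180 with an estimated correlation). Of the cell type markers outside microglia, Uchl1, a deubiquitinating enzyme, rose (0.43) and Aldoc, a glycolytic aldolase, fell (-0.22) (limma adjusted p of 0.00426 and 0.0319), the latter in only 2 of the 6 fits with 1 library left out. The heat shock and ribosomal protein lists had 0 of 13 and 0 of 30 genes past the threshold over all genes or adjusted over the list alone (camera adjusted p of 0.748 and 0.240, adjusted p = 0.928 and 0.826 with an estimated correlation).

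In the values as deposited camera gave no call for the other lists with CON-BDEV, although single members changed. In the vesicle biogenesis and endocytosis list Cd63, a tetraspanin of late endosomes, rose by 0.37, with 2 of 23 higher and 0 lower (3 and 0 adjusted over the list alone). Its camera adjusted p was 0.0505, with adjusted p = 0.357 with an estimated correlation. Disease-associated microglia genes had 3 of 21 higher and the lectin Lgals3 (-0.18) lower (8 and 3 adjusted over the list alone; camera adjusted p of 0.319, adjusted p = 0.611 with an estimated correlation). Glycolysis and hypoxia genes had 4 of 24 lower and 0 higher (5 and 3 adjusted over the list alone; camera adjusted p of 0.0709, adjusted p = 0.499 with an estimated correlation), with the mitophagy gene Bnip3 at -0.53. Among immediate early genes 3 of 21 rose, Fosl1 by 0.44, and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p of 0.407, adjusted p = 0.611 with an estimated correlation). The p53 list had Gadd45a, a DNA damage sensor, higher (0.96) and Sesn1 lower (-0.23) of 16 (3 and 5 adjusted over the list alone). The extracellular matrix list had the collagen Col4a1 higher (0.34) and the elastase Mmp12 lower (-0.57) of 9 (also 1 and 1 adjusted over the list alone). Their camera adjusted p was 0.435 and 0.921, with adjusted p = 0.611 and 0.928 with an estimated correlation. Antigen presentation genes had 2 of 16 higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p of 0.272, adjusted p = 0.446 with an estimated correlation). G1/S genes had Mcm7, a replication helicase subunit, lower (-0.18) and 0 of 22 higher (also 1 and 0 adjusted over the list alone; camera adjusted p of 0.435, adjusted p = 0.853 with an estimated correlation). Nuclear-retained and non-coding RNAs had 0 of 7 past the threshold (1 higher and 2 lower adjusted over the list alone), and neuronal markers had Uchl1 alone of 5 (also 1 and 0 adjusted over the list alone). Both had a camera adjusted p of 0.435, with adjusted p = 0.611 with an estimated correlation. The astrocyte, oligodendrocyte, endothelial, synaptic and histone lists kept 1 to 4 genes and were not tested as lists. Some lists without a call passed camera in other settings, or passed by fry, a different test. With the library-name number as a block the ribosomal list had an adjusted p of 0.0238 (median -0.04), and 0.0265 without CON-BDEV replicate 3. The inflammasome list had 0.0340 with the replicate number as a block, 0.0307 after quantile normalization, 0.0360 without Vehicle replicate 3 and 0.0208 without CON-BDEV replicate 1. The vesicle biogenesis list had 0.0418 without Vehicle replicate 1, 0.0443 without CON-BDEV replicate 2 and a fry adjusted p of 0.0372. Glycolysis and hypoxia had 0.0496 after quantile normalization, 0.0418 without Vehicle replicate 1 and 0.0171 without CON-BDEV replicate 1, and G1/S had 0.0250 without CON-BDEV replicate 1.

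In all, 597 of 10535 genes changed with CON-BDEV, 401 higher and 196 lower, with a median absolute log2 fold change of 0.31. With 1 FPKM added, which shrinks the changes of genes with low values, 18 of them, all higher, had at least 1. After quantile normalization 550 changed, 301 higher (54.7%) and 249 lower, against 67.2% higher as deposited. At an unadjusted p under 0.05 there were 2476 genes. The 3 libraries of each group did not overlap in 29.3% of genes, where chance gives 10%, and in all 597 called genes. The authors' Cuffdiff q was under 0.05 for 497 genes, of which 317 were among the 597 and 0 pointed the other way. The count depended on single libraries: it was 110, 84 and 121 without Vehicle replicates 1, 2 and 3, and 1067, 905 and 133 without CON-BDEV replicates 1, 2 and 3. It was 112 with no filter on low values and 275 with the number in the library name as a block. Of 71 calls among the genes named by rule, 19 held without each of the 6 libraries, including Nqo1, Gclm, Slc7a11, Slc48a1, Ccl7, Ccl2, Ccl9, Cd36, Lipa, Insig1, Scd2, Srebf1, Abca1 and Uchl1. Hmox1 missed the threshold without Vehicle replicate 2, without Vehicle replicate 3 and without CON-BDEV replicate 3, with a highest adjusted p of 0.0526 without Vehicle replicate 3. The highest adjusted p was 0.0755 for C1qc and 0.0687 for Arg1, both without CON-BDEV replicate 3, 0.107 for Ccl4 without Vehicle replicate 2, and 0.0592 for Fasn and Lss without Vehicle replicate 3.

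SE-BDEV against Vehicle asked the same of vesicles named for status epilepticus. Of 23 NRF2 and oxidative stress genes kept, 18 rose and 1 fell. Of 24 cholesterol synthesis and SREBP targets kept, 18 fell and 0 rose. As lists, both again missed the threshold of camera with an estimated correlation (adjusted p = 0.140 and 0.239), and both passed by fry (fry adjusted p of 0.00203 and 0.0132). Nqo1 rose to 8.97 ± 1.99 FPKM from 0.606 ± 0.205 FPKM (n = 3 per group), Gclm to 188 ± 26.4 from 42.2 ± 2.03 FPKM, Slc7a11 to 26.7 ± 3.56 from 6.14 ± 0.113 FPKM and Hmox1 to 497 ± 161 from 140 ± 3.37 FPKM. Their log2 fold changes were 2.62, 2.12, 1.95 and 1.77, with limma adjusted p of 6.61e-06, 2.12e-06, 2.12e-06 and 0.000301. For Nqo1 the authors' log2 fold change was 3.89 with a q of 0.605. The listed locus of Nqo1 spans more than 1 gene, and the added 1 FPKM shrinks the value given here. Slc48a1, a heme transporter, rose by 1.44, and Agt, the angiotensin precursor, by 1.35. Insig1 fell to 40.4 ± 9.52 from 78.4 ± 1.05 FPKM and Scd2 to 325 ± 25.4 from 595 ± 16.4 FPKM, by 0.97 and 0.88 on the log2 scale, with limma adjusted p of 0.0032 and 1.71e-05. Fdps, an enzyme of isoprenoid synthesis, fell to 288 ± 19.1 from 441 ± 12.3 FPKM. In mm9 Fdps lies on chromosome 3 from 88897510 to 88905889 and Slc48a1 on chromosome 15 from 97614796 to 97674933.

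With SE-BDEV 18 of 23 NRF2 and oxidative stress genes rose and 1 fell (19 and 1 adjusted over the list alone; median 0.65, camera adjusted p of 2.44e-22, adjusted p = 0.140 with an estimated correlation). Of 24 cholesterol synthesis and SREBP targets 18 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.46, camera adjusted p of 1.48e-17, adjusted p = 0.239 with an estimated correlation), among them Pmvk of the mevalonate pathway (-0.61). The LXR list had 6 of 13 genes lower, Srebf1 (-0.66) and Abca1 (-0.45) among them, and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p of 0.00377, adjusted p = 0.235 with an estimated correlation). In the phagocytosis and lysosome list 14 of 30 genes rose and 0 fell (16 and 1 adjusted over the list alone; camera adjusted p of 5.02e-06, adjusted p = 0.239 with an estimated correlation), with Cd36 (1.37), Lipa (0.83), Itgav (0.57) and the scavenger receptor Msr1 (0.49) the largest. The alternative activation list had 8 of 15 higher and Arg1 (-0.60) lower (also 8 and 1 adjusted over the list alone; camera adjusted p of 1.22e-05, adjusted p = 0.140 with an estimated correlation). Among 7 chemokines Ccl7 (1.48) and Ccl2 (0.85) rose and Ccl4 (-0.88) and Ccl9 (-0.77) fell (also 2 and 2 adjusted over the list alone; camera adjusted p of 0.702, adjusted p = 0.838 with an estimated correlation). Complement genes had 5 of 11 higher, C1qc by 0.88, C1qa by 0.76 and C1qb by 0.50, and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p of 0.107, adjusted p = 0.349 with an estimated correlation). C1qa was near the filter, with 0.495 ± 0.298 FPKM in Vehicle and 1.51 ± 0.250 FPKM with SE-BDEV, and fell under it without any 1 of the SE-BDEV libraries. The added 1 FPKM shrinks its log2 fold change, which was 1.56 with a pseudocount of 0.1 FPKM. Il1b rose from 5.18 ± 0.183 to 7.50 ± 0.637 FPKM (log2 fold change 0.46, limma adjusted p of 0.00313) and Ptgs2, an enzyme of prostaglandin synthesis, by 0.88, while Tnf had 0.04 (limma adjusted p of 0.692). The pro-inflammatory list had 4 of 23 genes higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p of 0.107, adjusted p = 0.503 with an estimated correlation). The inflammasome list had 2 of 11 higher, Casp1 (0.48) and Il1b, and 0 lower (2 and 1 adjusted over the list alone; camera adjusted p of 0.0677, adjusted p = 0.239 with an estimated correlation).

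Microglia and macrophage markers rose in 10 of 24 cases and fell in 1 with SE-BDEV (12 and 1 adjusted over the list alone; camera adjusted p of 0.000157, adjusted p = 0.140 with an estimated correlation). Homeostatic microglia genes rose in 4 of 9, Csf1r (0.27) and Mertk (0.23) among them, with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p of 0.00184, adjusted p = 0.140 with an estimated correlation). Unfolded protein response genes had 8 of 24 higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p of 1.55e-05, adjusted p = 0.140 with an estimated correlation), with Herpud1 (0.48), Atf5 (0.38) and Calr (0.35) named by the rule. The vesicle biogenesis and endocytosis list had 4 of 23 higher, Cd63 (0.33) and Cd81 (0.21) among them, both tetraspanins of vesicles, and 0 lower (also 4 and 0 adjusted over the list alone). Its camera adjusted p of 0.0207 was 0.0734 without Vehicle replicate 2, 0.0636 without SE-BDEV replicate 3 and 0.0562 after quantile normalization, with adjusted p = 0.349 with an estimated correlation. G2/M genes had 5 of 22 lower, Cdc20 (-0.26), Cenpf (-0.20), Kif20a (-0.19) and Plk1 (-0.19) among them, and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p of 1.54e-05, adjusted p = 0.239 with an estimated correlation). Glycolysis and hypoxia genes had 7 of 24 lower and 3 higher (7 and 4 adjusted over the list alone). Their camera adjusted p of 0.0370 was 0.0705 without Vehicle replicate 3, 0.0742 without SE-BDEV replicate 2 and 0.0710 after quantile normalization, with adjusted p = 0.279 with an estimated correlation. Among them were Bnip3 (-0.57) and Egln3 (-0.44), both induced by hypoxia and lower, and the growth factor Vegfa (0.35), which was higher. Ribosomal proteins had 0 of 30 genes past the threshold over all genes or adjusted over the list alone, but all 30 had a negative value (median -0.08, camera adjusted p of 1.22e-05, adjusted p = 0.279 with an estimated correlation). Type I interferon genes had 2 of 18 lower, Ifitm3 (-0.52) and Dhx58 (-0.33), and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p of 0.0765, adjusted p = 0.349 with an estimated correlation). The oxidative phosphorylation and heat shock lists had 0 of 28 and 0 of 13 genes past the threshold over all genes or adjusted over the list alone (camera adjusted p of 0.322 and 0.735, adjusted p = 0.405 and 0.842 with an estimated correlation). Of the cell type markers outside microglia, Uchl1 (0.39), Gata3 (0.32), Elavl4 (0.24), Flt1 (0.26) and Camk2a (0.22) rose and Aldoc (-0.26), Cnp (-0.26) and Syn1 (-0.26) fell. Their limma adjusted p ran from 0.000787 (Uchl1) to 0.0433 (Elavl4). Of the 6 fits with 1 library left out, Uchl1, Aldoc and Cnp passed in all 6, Camk2a in 5, Gata3 and Flt1 in 3, Syn1 in 1 and Elavl4 in 0.

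In the remaining lists camera gave no call with SE-BDEV in the values as deposited. Disease-associated microglia genes had 5 of 21 higher, the cathepsin inhibitor Cst7 (0.29) and the growth factor Igf1 (0.25) among them, and 2 lower, Lgals3 and the lipid carrier Fabp5 (both -0.23). Adjusted over the list alone there were 8 and 3, with a camera adjusted p of 0.137 and adjusted p = 0.503 with an estimated correlation. Immediate early genes had Fos (0.47) and 3 others of 21 higher and 2 lower, among them Jund (-0.56), another AP-1 subunit (7 and 4 adjusted over the list alone; camera adjusted p of 0.346, adjusted p = 0.503 with an estimated correlation). Antigen presentation genes had 2 of 16 higher and 2 lower, H2-Q4 (-0.30) and H2-K1 (-0.22), class I genes with similar copies (also 2 and 2 adjusted over the list alone; camera adjusted p of 0.574, adjusted p = 0.607 with an estimated correlation). The p53 list had 2 of 16 higher, Gadd45a (0.80) the larger, and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p of 0.533, adjusted p = 0.607 with an estimated correlation). The extracellular matrix list had 2 of 9 higher and Mmp12 (-0.54) lower (2 and 2 adjusted over the list alone; camera adjusted p of 0.755, adjusted p = 0.842 with an estimated correlation). G1/S genes had Cdc45 (0.19) higher and Mcm7 (-0.20) lower of 22 (0 and 1 adjusted over the list alone; camera adjusted p of 0.0709, adjusted p = 0.547 with an estimated correlation). Non-coding RNAs had Snhg1 (0.47) higher and Gas5 (-0.25) lower of 7 (1 and 2 adjusted over the list alone; camera adjusted p of 0.382, adjusted p = 0.503 with an estimated correlation). Neuronal markers had 3 of 5 higher and 0 lower (3 and 2 adjusted over the list alone; camera adjusted p of 0.273, adjusted p = 0.405 with an estimated correlation). Some lists without a call passed in other settings. The G1/S list had a camera adjusted p of 0.00469 (median -0.08) with the library-name number as a block and 0.0249 after quantile normalization. It also had 0.0296, 0.0350 and 0.0253 without Vehicle replicate 2, SE-BDEV replicate 2 and SE-BDEV replicate 3. Without SE-BDEV replicate 3 the pro-inflammatory list had a camera adjusted p of 0.0121 (median 0.08), the inflammasome list 0.0255 and type I interferon 0.0424, and the inflammasome list had 0.0376 without Vehicle replicate 3. By fry the adjusted p was 0.0198 for the inflammasome, 0.0192 for the complement and 0.00630 for the neuronal list.

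In all, 1253 of 10535 genes changed with SE-BDEV, 712 higher and 541 lower, with a median absolute log2 fold change of 0.25. With 1 FPKM added, 19 of them, all higher, had at least 1. That addition shrinks the changes of genes with low values. In the authors' values Ankrd37 went from 5.33 to 2.32 FPKM, a log2 fold change of -1.20 (authors' q of 0.448). After quantile normalization 1226 genes changed, 634 higher (51.7%) and 592 lower, against 56.8% higher as deposited. At an unadjusted p under 0.05 there were 2886 genes. The groups did not overlap in 32.8% of genes, where chance gives 10%, and in 1251 of the 1253 called genes. The authors' Cuffdiff q was under 0.05 for 617 genes, of which 483 were among the 1253 and 0 pointed the other way. The count was 501, 601 and 678 without Vehicle replicates 1, 2 and 3, 726 with no filter on low values, and 830 in 1 fit of all 9 libraries. Of 91 calls among the genes named by rule, 52 held without each of the 6 libraries, including Nqo1, Gclm, Slc7a11, Hmox1, Il1b, Cd36, Lipa, C1qc, Arg1, Insig1, Scd2 and Fdps. In contrast 33, 33 and 30 of the 91 were lost without Vehicle replicates 1, 2 and 3 and 20, 18 and 9 without SE-BDEV replicates 1, 2 and 3.

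**Figure D1:**
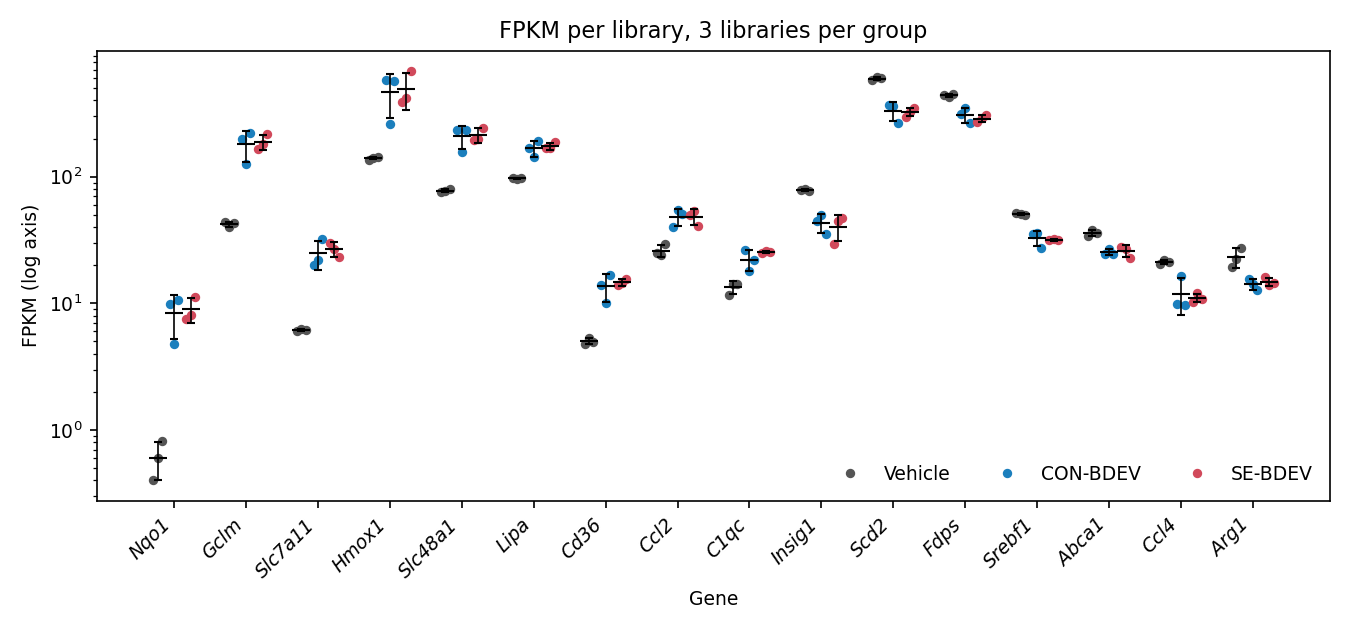
FPKM (log axis) of 16 genes in each of the 9 libraries, with the mean and SD of the 3 libraries of each group as bars. Gclm had a mean of 42.2 FPKM in Vehicle and of 181 and 188 FPKM with CON-BDEV and SE-BDEV, and Scd2 had 595, 332 and 325 FPKM.

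**Figure D2:**
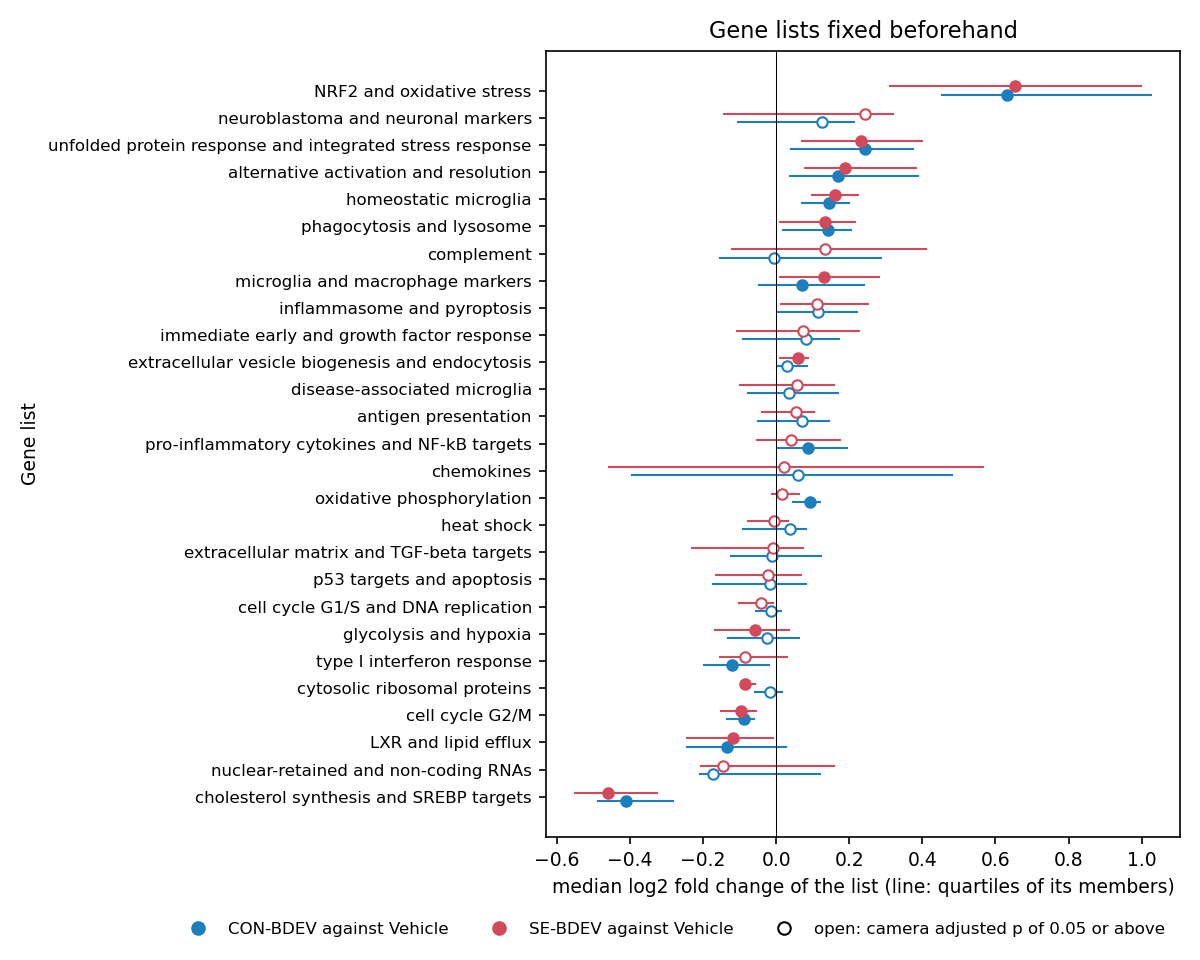
Median log2 fold change of 27 gene lists against Vehicle for CON-BDEV and SE-BDEV, with lines for the quartiles of each list's members and filled points for a camera adjusted p under 0.05 with the preset correlation. The NRF2 and oxidative stress list was highest (0.63 and 0.65) and the cholesterol synthesis and SREBP list lowest (-0.41 and -0.46).

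SE-BDEV against CON-BDEV bears on the study's title, which says that status epilepticus alters what the vesicles do. No gene passed the threshold among 10532 tested by limma. The antioxidant and sterol genes were at like levels with both preparations. Nqo1 had 8.96 ± 1.99 FPKM with SE-BDEV and 8.39 ± 3.19 FPKM with CON-BDEV (n = 3 per group), a log2 fold change of 0.13, and Hmox1, Gclm, Insig1 and Scd2 had 0.12, 0.09, -0.11 and -0.02, all with a limma adjusted p of 0.999. Il1b had 7.49 ± 0.637 against 6.50 ± 0.973 FPKM, a log2 fold change of 0.19 (limma adjusted p of 0.999), although it passed against Vehicle with SE-BDEV alone. The lowest p belonged to Srp54a, which encodes a subunit of the particle that targets secretory proteins, with 0.894 ± 0.213 FPKM with SE-BDEV and 2.06 ± 0.156 FPKM with CON-BDEV (log2 fold change -0.70, adjusted p of 0.111). It lies on chromosome 12 from 56256091 to 56365681 in mm9 and has close copies, so its reads may be shared. The added 1 FPKM shrinks its log2 fold change, as its values are near 1 FPKM. Cox7a1, a subunit of cytochrome c oxidase, came next (-0.54, adjusted p of 0.478), followed by Coprs (-0.28, adjusted p of 0.478), Rpp21 (-0.37) and Hypk (-0.18), both with an adjusted p of 0.934. On the higher side Zfp467 (0.42), Morn2 (0.29), Ugt1a6b (0.48), Ago3 (0.28) and Clk2-scamp3 (0.23) had adjusted p from 0.934 to 0.991.

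Of the 27 lists tested, 2 moved between the preparations, both by little. Oxidative phosphorylation genes were lower with SE-BDEV by a median of -0.045 (camera adjusted p of 1.41e-07, adjusted p = 0.138 with an estimated correlation, fry adjusted p of 0.0230), with 0 of 28 genes past the threshold over all genes and 3 lower adjusted over the list alone. Cytosolic ribosomal protein genes were lower by a median of -0.052 (camera adjusted p of 4.95e-07, adjusted p = 0.868 with an estimated correlation, fry adjusted p of 0.941), with 0 of 30 genes past either threshold, and the camera adjusted p was 0.397 after quantile normalization. Both lists hold short transcripts, with median lengths of 1553 and 1107 nt against 3366 nt for other genes, and the median log2 fold change over 5 equal groups of genes by length rose from -0.034 in the shortest to 0.030 in the longest. The NRF2 list had a median of 0.03 and the cholesterol synthesis and SREBP list one of -0.03 (camera adjusted p of 0.364 and 0.414, adjusted p = 0.988 for both with an estimated correlation), with 0 genes past either threshold. Single libraries moved them: without CON-BDEV replicate 3 the NRF2 median was 0.08 (adjusted p of 0.00121) and the SREBP median -0.14 (adjusted p of 5.55e-08), without CON-BDEV replicate 2 the NRF2 median was -0.07 (adjusted p of 0.0290), and without SE-BDEV replicate 3 the SREBP median was -0.08 (adjusted p of 0.00133). The phagocytosis list had a median of 0.02 and the alternative activation list one of 0.06 (camera adjusted p of 0.328 and 0.153, adjusted p = 0.868 for both with an estimated correlation), with adjusted p of 0.0144 and 0.0357 without SE-BDEV replicate 2, and of 0.0212 for alternative activation without CON-BDEV replicate 3. After quantile normalization 4 lists were higher with SE-BDEV, microglia and macrophage markers (median 0.06, camera adjusted p of 0.00711), disease-associated microglia (0.05, 0.00733), phagocytosis (0.05, 0.00553) and NRF2 (0.06, 0.0133). As deposited, the microglia and macrophage markers had a camera adjusted p of 0.328 and disease-associated microglia 0.945, with adjusted p = 0.868 and 0.988 with an estimated correlation. Heat shock genes were lower without CON-BDEV replicate 2 (-0.07, 0.0290) and G1/S genes without CON-BDEV replicate 3 (-0.05, 0.00756). With all libraries these 2 lists had camera adjusted p of 0.589 and 0.328, and adjusted p = 0.988 for both with an estimated correlation.

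At an unadjusted p under 0.05 there were 509 genes, and the groups did not overlap in 7.94% of genes, where chance gives 10%. Only limma was run on the genes of this comparison. The median 95% confidence interval reached 0.13 to either side of a gene's log2 fold change. In tests on simulated data with these group sizes limma found 94.0% of 50 genes changed 1.5-fold and 36.0% of 50 genes changed 1.2-fold. The same data also held 50 genes changed 3-fold, all found, and such calls loosen the adjusted threshold for the other genes. No gene passed in the real comparison, so the threshold there was stricter and these shares may be too high for it. Srp54a, with a log2 fold change of -0.70, did not pass (limma adjusted p of 0.111). Small differences, and larger ones in few genes, could thus have been missed. A single gene passed without CON-BDEV replicate 1 (Hist1h2bh, log2 fold change -0.97) and without SE-BDEV replicate 2 (Srp54a, -0.79), where Hist1h2bh was chosen after its values were seen.

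The effects of both preparations against Vehicle were close to each other across genes. Over 10508 genes, Pearson's r of the log2 fold changes was 0.859 and Spearman's rho 0.823, and 81.6% of genes had the same sign. Both comparisons used the same 3 Vehicle libraries, which alone gave a mean r of 0.503, a rho of 0.462 and 66.6% in 100 simulated draws with no effect of the vesicles. The covariance was 0.0223 against 0.00469 in the simulation. Among calls, 313 genes were higher with both preparations, 159 were lower with both and 0 went opposite ways. Independent lists would share 27.0 and 10.1, but the shared Vehicle libraries raise this. Top lists of the same sizes shared a mean of 137 (highest 163) and 69.3 (highest 86) in 100 simulated draws with no effect. All of these draws took noise separately for each gene, so with correlated genes they could vary more and the highest values be larger. The draws also gave the 3 groups the same spread. In the data the mean variance on the log2 scale was 0.0101 in Vehicle, 0.0182 with CON-BDEV and 0.0132 with SE-BDEV, which may shift the simulated values. Genes called higher with both included Nqo1, Gclm, Slc7a11, Cd36, Lipa and Ccl2, and genes called lower with both included Insig1, Scd2, Srebf1, Abca1, Ccl4 and Arg1. In a fit of all 9 libraries, 1336 of 10532 genes differed between the mean of both preparations and Vehicle, 799 higher and 537 lower, a comparison added after the data were seen. That count was 437, 481 and 622 without Vehicle replicates 1, 2 and 3. Genes are not independent replicates, and the 3 Vehicle libraries are too few to give each comparison its own controls.

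**Figure D3:**
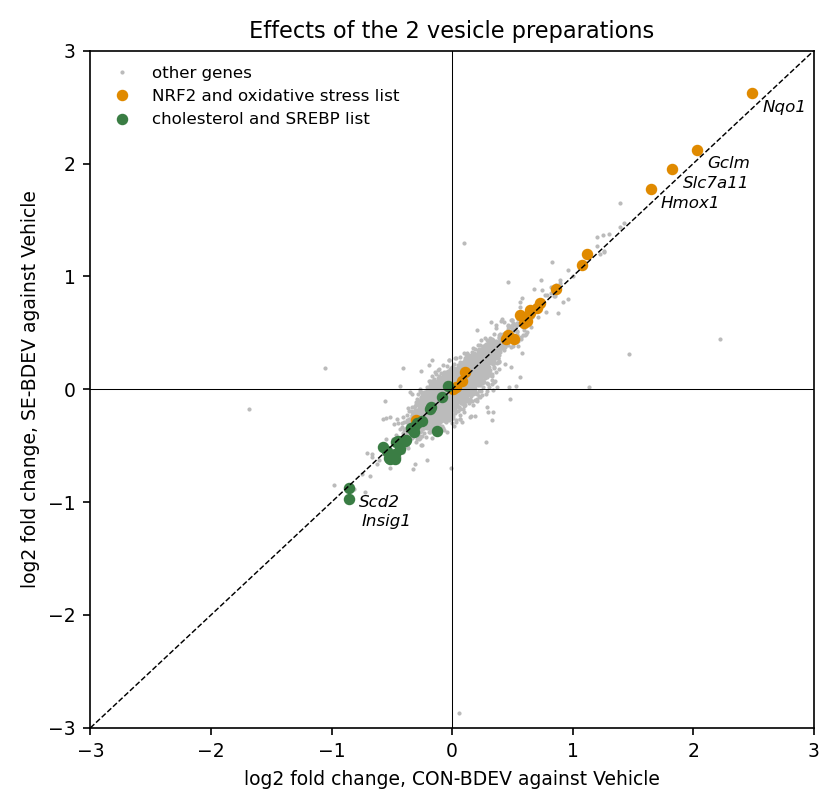
Log2 fold change against Vehicle with SE-BDEV (vertical) and with CON-BDEV (horizontal) for 10508 genes, with the NRF2 and oxidative stress list in orange, the cholesterol and SREBP list in green and a dashed line where both are equal. Nqo1 lies at 2.49 and 2.62 and Insig1 at -0.86 and -0.97, and Pearson's r across genes was 0.859.

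Ferritin, the iron storage protein, could be compared only in part. Fth1, its heavy chain (mm9 chromosome 19 from 10055090 to 10059601), had 13710 ± 747 FPKM in Vehicle (n = 3) and was listed at 0 in both vesicle groups, and Ftl1, its light chain (chromosome 7 from 52713314 to 52715256), had 12349 ± 265 FPKM in Vehicle and was listed at 0 with CON-BDEV. The deposited tables mark these 3 group values with Cuffdiff's status for too many fragments to estimate, so the zeros are not expression values and were left out. Where it was estimated, Ftl1 had 13943 ± 549 FPKM with SE-BDEV, 1.13-fold the Vehicle mean (log2 fold change 0.17, limma adjusted p of 0.0337).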

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

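Chosen only after the result was seen were the test of a larger spread between the CON-BDEV libraries, the test of the SREBP list with the library-name number, and the splits of 6 libraries. A first such SREBP test counted the calls that were kept. It gave 53.3%, between its 2 outcomes, and was replaced by the test on the list's median below, whose limits were set when the medians before and after were already known. The results below were singled out because a direct test of SE-BDEV against CON-BDEV gave a difference between the vesicle groups. They are the oxidative phosphorylation list, with a median log2 fold change of -0.045, and the list of cytosolic ribosomal proteins, with a median of -0.052.

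Both of these lists hold short transcripts, so transcript length was set against a biological difference between the preparations. Other genes matched to the oxidative phosphorylation genes on length and expression showed 92.6% of the list's median shift (95% confidence interval over genes 42.2 to 119). Those matched to the ribosomal genes showed 103% (74.4 to 146). A single library was argued against, as the highest camera adjusted p with any library left out was 3.79e-05 for oxidative phosphorylation (without CON-BDEV replicate 3) and 0.00536 for the ribosomal list (without CON-BDEV replicate 2), although this rests on the preset correlation: with an estimated correlation the adjusted p was 0.138 and 0.868, by fry 0.0230 and 0.941, and after quantile normalization the ribosomal list had 0.397. A trend with transcript length, such as a difference in RNA integrity or library preparation, may therefore account for both shifts. What made the trend was not tested, and a change of mitochondrial or ribosomal genes beyond it stays open.

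More genes passed against Vehicle with SE-BDEV (1253) than with CON-BDEV (597). With 1 spread shared by all 9 libraries the counts were 830 and 794, a ratio of 1.05, so a larger spread between the CON-BDEV libraries may account for most of the excess. A weaker response to CON-BDEV stays open, as the median ratio of its log2 fold changes to those of SE-BDEV was 0.978 over the 1336 genes that differed between both preparations and Vehicle (95% confidence interval over genes 0.964 to 0.992), but 0.883 without CON-BDEV replicate 3 and 1.10 without CON-BDEV replicate 2. The shared Vehicle libraries pull this ratio towards 1, in simulated draws from 0.8 to a mean of 0.814, or to 0.862 with effects at 0.5 of their size. Why the CON-BDEV libraries spread more was not tested.

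The NRF2 list was higher and the SREBP list lower with both preparations, and a technical source was set against a response to the vesicles (camera adjusted p = 0.180 and 0.267 with an estimated correlation with CON-BDEV, and 0.140 and 0.239 with SE-BDEV). The fry adjusted p was 0.0073 and 0.0372 with CON-BDEV, and 0.00203 and 0.0132 with SE-BDEV. For 10 abundant brain transcripts, RNA of brain cells carried along was argued against. They gained -0.279% of the NRF2 list's gain in FPKM, a sum pulled down by Aldoc and Cnp, which the cells express. Those that rose, Camk2a the most, together gained 0.0855% (CON-BDEV) and 0.123% (SE-BDEV), and the 7 under 2 FPKM in Vehicle 0.00794% and 0.0148%. The neuronal marker Uchl1, which the cells also express, is not among the 10. It rose from 73.7 FPKM in Vehicle to 100 with CON-BDEV and 97.0 with SE-BDEV, while the neuronal markers Nefh and Ina went the other way. These genes were not weighed. A batch marked by the number in the library name was argued against for the NRF2 list, as at least 94.4% of its passing genes still passed with that number in the fit. For the SREBP list it was argued against as the whole cause. The list's median kept 95.3% of its size with CON-BDEV and 111% with SE-BDEV. The 95% confidence intervals, 92.1 to 99.2 and 106 to 117, cover only the spread over genes and not between libraries. With a library left out the share ran from 64.1% (without Vehicle replicate 3) to 107% with CON-BDEV, and from 104% to 137% with SE-BDEV. Only 8 of 15 calls held with CON-BDEV, against 18 of 18 with SE-BDEV. With CON-BDEV the median of the 15 moved from -0.47 to -0.46, their median standard error from 0.0862 to 0.0936 and the degrees of freedom from 4 to 3. Any response to added vesicles, to their medium or to handling stays open, since Vehicle is the only control group.

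The splits bear on the counts of genes. The 10 splits of 6 libraries are too few for a share under 0.05: with CON-BDEV and Vehicle the real split gave 597 genes and the highest other 0 (1 of 10 splits as large), with SE-BDEV and Vehicle 1253 and 0 (1 of 10), and with SE-BDEV and CON-BDEV 0 and 1. As the real count there was 0, all 10 of 10 splits had to be as large, which says nothing. The 84 splits of 9 libraries into 6 and 3 were fitted as 2 groups. Only the real split of both preparations against Vehicle gave as many genes as its 1414 (1336 when fitted as 3 groups), and the highest other gave 1. A random split of these libraries would thus rarely give as many genes (1 of 84 splits). Since the libraries may not be separate cultures, chance differences between cultures cannot be judged this way.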

How the results depend on the processing

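Keeping genes with failed estimates, leaving out short-RNA genes and comparing both preparations with Vehicle were chosen after the data were seen. With CON-BDEV against Vehicle, 597 genes became 112 with no filter on low values (101 of them among the 597), 364 with the replicate number (335 shared) and 275 with the library-name number (271 shared) as a block, 18 with a log2 fold change of at least 1, and 84 to 1067 with 1 library left out. Other settings gave 416 to 794. With SE-BDEV against Vehicle, 1253 became 726 with no filter (654 shared), 830 in 1 fit of 9 libraries (828 shared), 617 by the authors' q, 19 with a log2 fold change of at least 1, and 501 to 1311 with 1 library left out. Other settings gave 1017 to 1260. For SE-BDEV against CON-BDEV, 0 genes became 1 without the mean-variance trend (Srp54a, adjusted p of 0.0484), 1 with failed estimates kept at 0 (Ftl1, listed at 0 with CON-BDEV), and 0 to 1 with 1 library left out. Against Vehicle 12 lists passed camera with each preparation and 0 with an estimated correlation, 11 to 14 in other settings with CON-BDEV and 11 to 15 with SE-BDEV. The loss with an estimated correlation was not limited to lists of correlated genes. With CON-BDEV the unfolded protein response list had an estimate of -0.01, yet its camera adjusted p went from 2.83e-05 to 0.180. With SE-BDEV homeostatic microglia genes had -0.03, and theirs went from 0.00184 to 0.140. Between the preparations 2 lists became 0 with an estimated correlation, 1 by fry, 5 after quantile normalization and 2 to 6 with 1 library left out. The NRF2 list median between the preparations, 0.03, was -0.067 (reversed) without CON-BDEV replicate 2 and 0.078 without CON-BDEV replicate 3. Both preparations against Vehicle gave 1336 genes, 437 to 1584 with 1 library left out and 18 with a log2 fold change of at least 1. Of 30 neuronal markers 5 reached 1 FPKM and 3 reached 5 FPKM. The correlation of both effects ran from 0.819 to 0.876. Of 71 named calls with CON-BDEV 57 were lost with no filter, 25 with the library-name number, 22 with the replicate number, 21 without the trend, 13 after quantile normalization, 5 with median centring and 9 in 1 fit of 9 libraries. Of 91 with SE-BDEV these were 32, 10, 10, 13, 5, 0 and 26. Leaving out a library also leaves fewer degrees of freedom, and otherwise the cause was not tested. At 29092000 to 33645000 fragments, 1 FPKM in a gene with 2 kb of exons stood for 58.2 to 67.3 fragments, and lower values for fewer.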

Other observations

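The list of iron and heme genes and its test were chosen only after the values of some of its genes were seen. Some genes of iron and heme handling rose with both preparations, and the list was not tested as a list. Of 24 such genes 20 were kept, with 9 higher with CON-BDEV, 11 with SE-BDEV and 0 lower, and a median log2 fold change of 0.23 with each. Blvrb, a reductase named for biliverdin, rose from 44.4 ± 0.745 FPKM in Vehicle to 106 ± 11.9 with CON-BDEV and 103 ± 7.53 FPKM with SE-BDEV (limma adjusted p of 0.000186 and 2.12e-06, n = 3 per group). The iron exporter Slc40a1 rose by 0.96 and 1.06, the lysosomal metal transporter Slc11a1 by 0.78 and 0.84, the porphyrin transporter Abcb6 by 0.73 and 0.75, and Bach1, a heme-sensing repressor, by 0.28 and 0.30. Blvra, the other biliverdin reductase of the list, did not pass, with 0.01 and -0.07 (limma adjusted p of 0.920 and 0.249). The rise of Blvrb thus does not show that the step from biliverdin to bilirubin rose. Each of these genes was chosen after its values were seen.

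A first hypothesis was that the vesicles load the cells with iron or heme. Iron loading lowers Tfrc, the transferrin receptor, since its mRNA is degraded when iron is plentiful. Tfrc had log2 fold changes of 0.39 with CON-BDEV (limma adjusted p of 0.0770) and 0.41 with SE-BDEV (limma adjusted p of 0.0132). Their 95% confidence intervals were 0.14 to 0.64 and 0.23 to 0.59, so Tfrc did not show the fall predicted for iron loading. This rests on the mRNA of a single gene, and whether another response raised Tfrc was not tested. The ferritin gene Fth1 had no estimate with either preparation and could not be weighed beside it. Heme signalling without free iron, or NRF2 alone, could still raise Hmox1, Blvrb and Slc40a1 and was not tested.

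A second hypothesis was that the vesicles deliver cholesterol, which would lower sterol synthesis genes and raise LXR targets. The higher of the 2 medians of 11 sterol synthesis genes kept was -0.43, but all 12 genes chosen belong to the SREBP list in which the fall was first seen, so this test decides nothing. The LXR list had medians of -0.14 and -0.12 with Abca1 lower, although sterol delivery might be expected to raise it. Cholesterol delivery stays open.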
